A study of Mus musculus with 52 samples.

How the data were processed

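The data are RNA-seq profiles of mouse spinal cord from mice carrying a mutant human SOD1 transgene, a model of amyotrophic lateral sclerosis, and from non-transgenic controls. Translating ribosomes were purified from motor neurons, astrocytes or oligodendrocytes through an EGFP-tagged ribosomal protein made in that cell type alone, and whole spinal cord RNA was profiled beside them, per the labels' protocols. There were 52 libraries in 13 groups of 3 to 6, read as 50 nt single ends from poly(A) RNA. The labels give 2 stages, disease onset and an early symptomatic stage, and name the ages of 8 and 11 months for the oligodendrocyte and whole spinal cord groups. All onset libraries are labelled male, while each 11-month group holds both sexes. The labels do not say that each library came from a separate animal, so the p-values measure the spread between libraries.

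The submitters' processing notes name TopHat2 2.0.8b, Cufflinks and Cuffdiff and the mouse build mm9, without the role of each tool or its settings. The authors deposited 6 tables with a value per gene and library, 1 table for each cell type or tissue at each stage, with gene coordinates on mm9. Each table listed 23697 genes, and 2 blank lines in each were not used here. The deposited values of the 11-month spinal cord table were FPKM, fragments scaled by transcript length and by mapped fragments, and were used as they stand. The deposited values of the other 5 tables are called FPKM too, but were a signal on a scale about 16774 times as high, by the median over genes of the ratio of the 8-month to the 11-month spinal cord libraries. The sources used here do not state why. The 4 tables of purified cells allow no such ratio, so that the factor holds there is an assumption. Those values were divided by that factor and are given as FPKM-equivalents. The design had assumed FPKM throughout, so the effective pseudocount and minimum level in these 5 tables rest on that factor.

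The 75th percentile of the non-zero values was nearly the same in every library of a table, at 21.9 to 22.3 in motor neurons, 22.5 to 23.5 in astrocytes, 22.1 to 22.9 and 23.2 to 24.9 in 8-month and 11-month oligodendrocytes, and 20.3 to 20.5 and 19.9 to 20.6 in 8-month and 11-month spinal cord. No label states a normalization that would give this. Absolute depth is unknown, since the values are not counts and low values gave the relative depth of libraries within a table alone. The deepest library of a table was 1.36 times the shallowest in motor neurons, 1.32 times in astrocytes, 1.30 and 1.21 times in 8-month and 11-month oligodendrocytes, and 1.27 and 1.66 times in 8-month and 11-month spinal cord. The gene with the highest value took up to 1.74%, 8.63%, 16.1%, 2.33%, 21.1% and 2.62% of a library's sum in the same order of tables. Some genes that are abundant elsewhere in a table were listed at or near 0 in a few libraries, among them Mbp in 1 control library of 11-month oligodendrocytes. There were 41, 36, 20, 142, 120 and 93 genes with such a value in the same order, and a value of 0 is therefore called listed at 0 and not read as absence of the transcript. A few genes of the lists are not reported here by name.

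Each comparison stayed within a table, since the tables were normalized separately, and levels set across tables carry that limit. Values were transformed to log2(value + 1), and genes with a mean of at least 1 over the libraries of the table were tested. Fold changes on this scale understate the change of low genes. Group means were compared with limma 3.58.1 in R 4.3.3, with moderated variances, an intensity trend and robust estimation, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. Every adjusted p of a gene below is limma's. The 11-month oligodendrocyte comparisons came from 1 fit of all 3 groups. Differences between effects were tested as contrasts of the within-table effects, on the genes kept in both tables. Errors beside means are SDs over libraries. Whether the lowest library of a group lay above the highest of the other was recorded beside the chance share of such genes.

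There were 38 gene lists, written from textbook knowledge before the data were examined, which cover stress responses, neuronal and synaptic genes, energy and lipid metabolism, immune genes and markers of the cell types of spinal cord. Of 688 list members, 685 matched a symbol in the tables, with older symbols matched by the same rule throughout. Ifi27 was matched in this way to Ifi27l1, which is doubtful, since that symbol names another gene of the family. There were 248 symbols listed more than 1 time. Lists with at least 5 tested members were compared with all other genes by limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison, and again with the correlation estimated from the data. Members past 0.05 were counted over all genes tested and adjusted over the list alone. No list was past 0.05 in any comparison with an estimated correlation, so every camera call below rests on the preset value.

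Genes named below follow a rule written at the same time as the lists. It takes Sod1, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups do not overlap, up to 4 members of each described list with the largest change past the threshold, and otherwise values of the 2 members with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p are given as values. A difference of effects has the 5 genes with the smallest p in each direction. Lists are described where camera called them, where at least 3 members passed, or where they mark the purified cell type. Not every gene the rule takes is printed. Where the text singles out a gene outside the rule, it says so.

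Alternatives were another pseudocount, another or no minimum level, median scaling, quantile normalization, no robust estimation, sample weights, the replicate number as a block, sex as a covariate, a fit of the compared groups alone, each library left out in turn, and other list tests. Alternatives added after the data were seen treated listed near-zero values as missing, left out doubted libraries, for genes and for the G85R lists, or left Ifi27 unmatched. Each fit was tested on simulated independent noise with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. Real libraries share structure, so their rates may differ. Recovery by comparison, at 0.5 and 1, was 87% and 96% in motor neurons, 66% and 96% in astrocytes, 77% and 95% in 8-month oligodendrocytes, 57% and 94% for G37R and 53% and 92% for G85R in 11-month oligodendrocytes, 38% and 87% between the mutations, 83% and 98% in 8-month and 67% and 90% in 11-month spinal cord. False calls were 7 of 190, 11 of 173, 21 of 193, 6 of 157, 5 of 150, 9 of 134, 9 of 190 and 5 of 162 in the same order, so they exceeded the 5% that the threshold allows in 8-month oligodendrocytes most, and in astrocytes and between the mutations. Camera called an unmoved simulated list at 0.05 in 8-month oligodendrocytes alone. For the differences of effects, with 200 genes changed by 1, 86.5% were recovered between the stages of oligodendrocytes, 90.5% between the stages of spinal cord, 94.5% between motor neurons and astrocytes, 92.5% between motor neurons and oligodendrocytes and 94% between astrocytes and oligodendrocytes. False calls were 12 of 185, 11 of 192, 12 of 201, 8 of 193 and 12 of 200 there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.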

Results

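Ribosome-bound RNA was profiled from motor neurons (4 control and 4 G37R libraries) and astrocytes (6 and 4) at disease onset. Oligodendrocytes were profiled at 8 months (5 and 4) and at 11 months (5 control, 3 G37R and 3 G85R libraries). Whole spinal cord RNA was profiled at 8 months (4 control and 4 G37R libraries) and at 11 months (3 and 3). G37R and G85R are mutations of SOD1, which encodes a cytosolic superoxide dismutase. The series title names a damage cascade from motor neurons to glia, so the comparisons ask which transcripts differ between mutant and control in each cell type and stage. They also ask whether the effects differ between them. Libraries of a group correlated at r = 0.932 to 0.989 across genes. Levels are means ± SD in FPKM-equivalents, mutant before control, and changes are differences of log2(value + 1) with their SE.

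In the control libraries, markers of the purified cell type lay above their whole spinal cord level at 8 months, across tables that were normalized separately. The 16 motor neuron identity genes, such as the acetylcholine synthesis and transport genes, had a median log2 ratio of 2.86 in motor neuron libraries, with 16 of 16 higher. There, astrocyte genes lay at -4.35, myelin genes at -3.35 and microglial markers at -2.88. Astrocyte homeostatic genes had a median of 1.07 in astrocyte libraries (15 of 18 higher), where myelin genes lay at -0.55 and microglial markers at -2.02. Myelin genes lay at 2.06 in 8-month and 2.01 in 11-month oligodendrocyte libraries (21 of 22 higher in both).

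Mouse Sod1, at chromosome 16, 90220986 to 90226569 (mm9), did not pass the threshold in any comparison, and the human transgene is not listed apart from it. Its level was 1350 ± 69.4 against 1473 ± 59.8 in motor neurons, 1167 ± 209 against 1066 ± 53.7 in astrocytes and 509.9 ± 21.6 against 526 ± 59.1 in 8-month oligodendrocytes. In 11-month oligodendrocytes it was 466 ± 83.1 in G37R and 452 ± 55.5 in G85R against 544 ± 65.2. In spinal cord it was 390.3 ± 26.2 against 398 ± 27.6 at 8 months and 428 ± 30.0 against 433 ± 31.9 at 11 months. The adjusted p-values in that order, with G85R against G37R before the spinal cord, were 0.133, 0.663, 0.900, 0.182, 0.197, 0.938, 0.875 and 0.991.

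Motor neurons of G37R mice at onset had more of the transcripts of injury and of the integrated stress response. Sprr1a, a cornified envelope gene induced in injured neurons (chromosome 3, 92287875 to 92289803), was at 77.9 ± 10.3 against 2.43 ± 1.16 (log2 change 4.59, SE 0.28, n = 4 and 4, adjusted p = 0.00168). Atf3, a transcription factor of stress and axon injury (chromosome 1, 192994175 to 193007212), was at 11.7 ± 2.44 against 1.36 ± 0.685 (2.46, SE 0.24, adjusted p = 0.00455). Fgf21, a stress-induced hormone, rose to 12.6 ± 4.52 from 0.772 ± 0.306, and the stress gene Nupr1 to 27.1 ± 6.14 from 6.99 ± 1.46. The peptide gene Adm2 was listed at 0 in all 4 controls and at 1.37, 1.60, 3.59 and 1.995 in the G37R libraries. Of 22 measured genes of the PERK/ATF4 stress response 16 rose and 0 fell (20 rose adjusted over the list alone), among them the serine synthesis genes Phgdh (1.23, SE 0.29) and Psat1 (0.93, SE 0.16). Camera gave the list an adjusted p of 9.62e-13, and 0.221 with an estimated correlation. Of 18 nerve injury genes 5 rose and 0 fell (10 rose adjusted over the list alone), including the neuropeptide Npy (1.16, SE 0.26) and the growth cone gene Gap43 (0.54, SE 0.13). That list had an adjusted p of 3.79e-06, and 0.221 with an estimated correlation. In the same libraries the glial filament gene Gfap was at 157 ± 65.4 against 49.4 ± 13.2.

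Genes of motor neuron identity and of synapses moved in both directions. Calca, which encodes the peptide CGRP, rose to 909 ± 73.6 from 584 ± 85.7 (0.65, SE 0.10), while Chodl, a marker of fast motor neurons (-0.46, SE 0.11), and the homeobox genes Isl2 (-0.31, SE 0.09) and Mnx1 (-0.27, SE 0.07) fell. Of 16 identity genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with an adjusted p of 0.0275 for a lower level and adjusted p = 0.611 with an estimated correlation. Of 20 presynaptic genes 1 rose and 4 fell, among them the calcium sensor gene Syt2 (-0.61, SE 0.13) and the vesicle protein gene Sv2c (-0.49, SE 0.11). The median of that list was 0.06 and its mean -0.02, with an adjusted p of 0.886 (0.939 with an estimated correlation). Of 16 glutamate receptor and postsynaptic genes 2 rose and 3 fell, with the kinase gene Camk2a at 0.71 (SE 0.15) and the receptor subunit gene Grin3a at -0.46 (SE 0.11). Its adjusted p was 0.671, for a lower level where the median was 0.01 (adjusted p = 0.821 with an estimated correlation). Among the largest falls were the muscarinic receptor gene Chrm2 (8.43 ± 1.68 against 15.8 ± 1.97), the potassium channel gene Kcnk9 (-0.84, SE 0.20) and the calcium channel gene Cacna1d (-0.74, SE 0.20).

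Lipid and energy genes of motor neurons parted in direction. Of 21 cholesterol synthesis genes 14 fell and 0 rose (16 fell adjusted over the list alone). Hsd17b7, an enzyme of the pathway (chromosome 1, 171879667 to 171899336), was at 8.05 ± 0.667 against 14.3 ± 1.23 (-0.75, SE 0.08, adjusted p = 0.00164), and Insig1 (-0.47, SE 0.07) and Sqle (-0.42, SE 0.06) fell with it. The list had a median of -0.27, an adjusted p of 1.82e-10, and 0.345 with an estimated correlation. Of 20 genes of glycolysis and lactate transport 5 rose and 0 fell (11 rose adjusted over the list alone), such as Ldha (0.44, SE 0.12) and the glucose transporter gene Slc2a1 (0.40, SE 0.10), with an adjusted p of 5.41e-05 (0.4996 with an estimated correlation). Of 32 genes of oxidative phosphorylation 5 fell and 0 rose, such as the respiratory chain gene Cox4i1 (2908 ± 122 against 3564 ± 130), with an adjusted p of 0.00810 (0.563 with an estimated correlation). Of 30 cytosolic ribosomal protein genes 15 fell and 0 rose (26 fell adjusted over the list alone), among them Rpl14 (-0.42, SE 0.07) and Rpl37 (-0.41, SE 0.08). The adjusted p was 5.86e-13, and adjusted p = 0.345 with an estimated correlation. Of 20 genes of fatty acid oxidation 3 rose, among them Hadhb (0.38, SE 0.07), with an adjusted p of 0.00147 (0.4996 with an estimated correlation). Of 15 LXR targets 1 rose, the sterol exporter gene Abcg1 (0.38, SE 0.08), and 2 fell, Scd1 and Nr1h3, with an adjusted p of 0.761 for a lower level where the median was 0.06 (adjusted p = 0.883 with an estimated correlation). Of 13 NRF2 and metal response genes 2 rose, Hmox1 (0.59, SE 0.13) and G6pdx, and 2 fell, Gclm and Mt3, with an adjusted p of 0.0553 (0.563 with an estimated correlation).

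Transcripts of other cell types were higher in the same G37R motor neuron libraries as all of these groups. Of the myelin genes 22 of 22 were higher, with a median of 0.52, and 2 of them rose, Cldn11 and Gm98 (11 adjusted over the list alone), with an adjusted p of 3.57e-06 and 0.504 with an estimated correlation. Astrocyte homeostatic genes had a median of 0.35, with 0 of 18 past the threshold by limma and Glul at 325 ± 90.7 against 200.6 ± 14.0 (adjusted p = 0.000736 for the list, 0.597 with an estimated correlation). Microglial and complement transcripts rose. Tyrobp, an adaptor of microglial receptors, was at 9.67 ± 4.42 against 1.48 ± 0.456 and the complement gene C1qa at 8.79 ± 3.95 against 1.79 ± 0.427. The lysozyme gene Lyz2 was at 6.21 ± 3.43 against 1.12 ± 0.257 and the protease gene Ctss at 7.59 ± 3.81 against 2.06 ± 0.654. Of measured genes, 3 of 5 homeostatic microglia markers (Fcer1g, Aif1, Fcgr3), 3 of 7 disease-associated microglia genes, 6 of 6 complement genes, 6 of 14 reactive astrocyte genes such as Vim (1.30, SE 0.25) and Timp1 (1.11, SE 0.17), 6 of 20 lysosome genes, 4 of 12 interferon genes and 2 of 11 interneuron markers (Gad2 and Pax2) rose, and 0 fell. Their adjusted p-values in that order were 0.000839, 0.000542, 5.41e-05, 0.0133, 0.0161, 0.000382 and 0.00147. For the same lists the adjusted p with an estimated correlation was 0.345, 0.345, 0.345, 0.345, 0.657, 0.4996 and 0.511. The interferon genes that rose include Ifi27l1, whose match to the listed Ifi27 is doubtful.

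Of 12303 genes tested in motor neurons 1582 passed the threshold, 798 higher and 784 lower in G37R, 29 of them at least 2-fold higher and 0 at least 2-fold lower. The groups did not overlap for 21.5% of genes, where chance gives 2.86%. Without the library labelled G37R 3 or G37R 4 the count was 579 or 589, without control 2, 3 or 4 it was 274, 342 or 472, and with the replicate number as a block it was 810. Left out together, as an alternative chosen after seeing the data, G37R 3 and G37R 4, the libraries with most glial transcripts (Gfap at 209 and 217, against 97.8 and 103 in G37R 1 and 2 and 38.4 to 68.5 in controls), brought the count to 261, of which 236 were among the 1582.

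**Figure D1:**
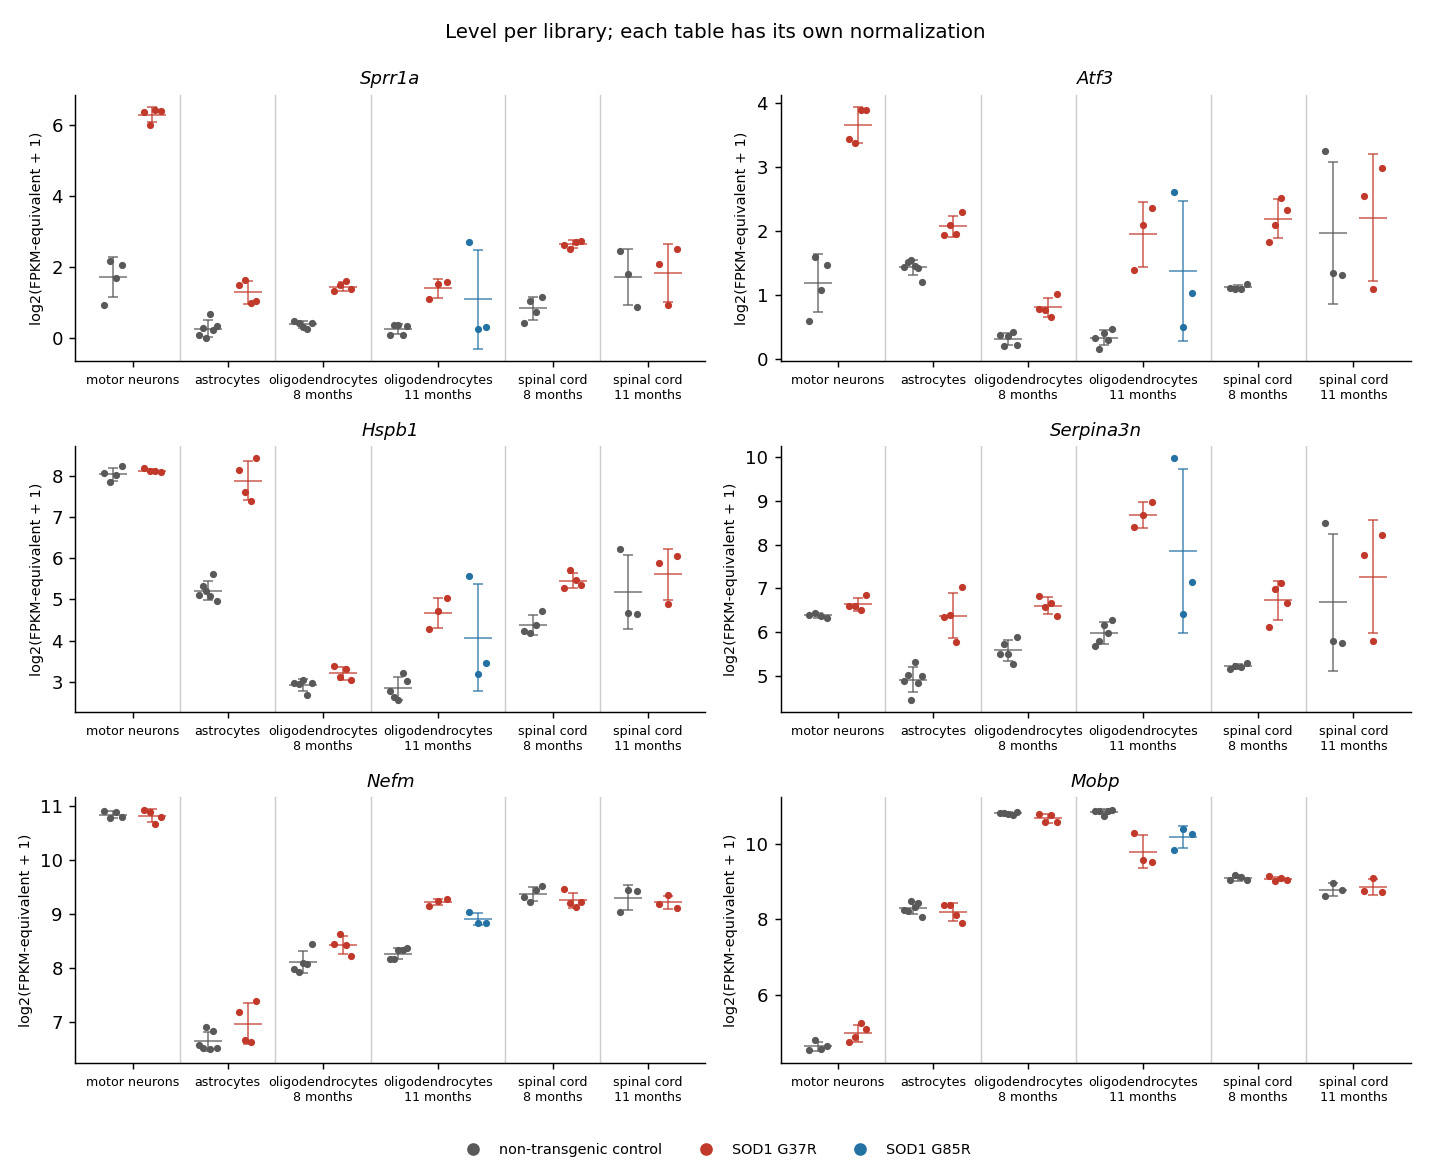
Level of 6 genes in each library (points, log2 of FPKM-equivalent + 1) with the mean and SD of each of the 13 groups (bars). Sprr1a was at 77.9 ± 10.3 in G37R and 2.43 ± 1.16 in control motor neurons, Hspb1 at 246 ± 80.9 and 36.6 ± 6.40 in astrocytes, and Mobp at 916 ± 295 and 1854 ± 78.4 in 11-month oligodendrocytes.

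Astrocytes of G37R mice at onset had more of the transcripts of reactive astrocytes. Hspb1, a small heat shock protein gene (chromosome 5, 136363788 to 136365433), was at 246 ± 80.9 against 36.6 ± 6.40 (2.67, SE 0.19, n = 4 and 6, adjusted p = 9.91e-05). Timp1, an inhibitor of matrix proteases, rose to 19.0 ± 6.69 from 3.46 ± 0.842 (2.11, SE 0.23), and Serpina3n, a protease inhibitor of reactive astrocytes, to 86.2 ± 31.5 from 29.7 ± 5.80 (1.46, SE 0.21). Of 24 reactive astrocyte genes 13 rose and 0 fell (19 rose adjusted over the list alone), with an adjusted p of 5.72e-21 and 0.0558 with an estimated correlation. The glucocorticoid target Fkbp5 (2.46, SE 0.45), S100a4 (1.86, SE 0.18), the galectin gene Lgals3 (1.68, SE 0.19) and Cebpd, a transcription factor of acute inflammation (1.65, SE 0.17), were among the largest rises. Of 18 astrocyte homeostatic genes 0 passed by limma, with a median of -0.01, Sox9 at 36.4 ± 4.17 against 49.6 ± 8.28 and Glul at 2219 ± 177 against 1835 ± 210 (adjusted p = 0.554 for the list, 0.853 with an estimated correlation). Among the largest falls were Fam181a (9.34 ± 2.86 against 25.8 ± 6.08), the oligodendrocyte lineage factor gene Olig2 (29.3 ± 7.82 against 51.8 ± 7.55) and Aven, an inhibitor of apoptosis (47.9 ± 6.08 against 87.5 ± 9.65). Plekho2 (-0.89, SE 0.12) and Fam123a (-0.78, SE 0.14) fell too.

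Stress and immune groups rose in astrocytes as well. Of 23 PERK/ATF4 genes 5 rose and 0 fell, among them the transcription factor gene Cebpb (1.46, SE 0.17), the mitochondrial folate enzyme gene Mthfd2 (1.36, SE 0.19), Nupr1 (1.29, SE 0.18) and Atf3 (0.64, SE 0.10). The adjusted p was 0.000114, and adjusted p = 0.0513 with an estimated correlation. Of 14 nerve injury genes 3 rose (Hspb1, Atf3 and Gap43, 8 adjusted over the list alone), with an adjusted p of 2.67e-05 (0.0513 with an estimated correlation). Of 16 interferon genes 6 rose (10 adjusted over the list alone), such as Isg15 (1.02, SE 0.18), Usp18 (0.80, SE 0.16) and Bst2 (0.78, SE 0.11), with an adjusted p of 5.44e-09 (0.105 with an estimated correlation). Of 23 lysosome genes 5 rose, of 7 antigen presentation genes 1 (H2-T23), of 8 cytokine and NF-kB genes 2 (Nfkbia and Cxcl12) and of 9 immediate early genes 2 (Junb at 13.2 ± 3.02 against 4.59 ± 0.448, and Egr1), with adjusted p-values of 1.36e-10, 0.00149, 0.00623 and 0.0448. The adjusted p of these lists was, with an estimated correlation, 0.243, 0.390, 0.105 and 0.390. Camera also called smaller shifts. Medians were 0.23 for ER chaperones (1 of 26 rose, Herpud1), 0.21 for cytosolic heat shock (1 of 14, Hspb1), 0.09 for the proteasome, 0.10 for oxidative phosphorylation, 0.11 for glycolysis, 0.20 for ribosomal proteins and -0.28 for cholesterol synthesis (0 members each), with adjusted p-values of 0.000659, 0.000832, 0.00188, 0.00515, 0.0111, 0.000103 and 0.000114. Their adjusted p lay, with an estimated correlation, between 0.390 and 0.601.

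Microglial transcripts moved with these groups in astrocyte libraries. Of 12 homeostatic microglia markers 5 rose, such as Fcer1g (1.35, SE 0.19), Fcgr3 (1.14, SE 0.10) and Olfml3 (1.10, SE 0.11), and 1 fell. Of 11 disease-associated microglia genes 5 rose, such as Lyz2 (1.69, SE 0.14), Tyrobp (31.1 ± 1.40 against 10.1 ± 2.18) and Trem2 (1.19, SE 0.13). Of 6 complement genes 4 rose, C1qa, C1qb, C1qc and Serping1. The adjusted p-values were 1.43e-07, 5.58e-09 and 6.86e-11, and with an estimated correlation the adjusted p was 0.122, 0.105 and 0.0589. Markers of pericytes, smooth muscle and fibroblasts (2 of 6 rose, Tagln and Kcnj8), of ependymal cells (0 of 6, Rsph1 at 10.2 ± 0.509 against 7.63 ± 1.20) and of interneurons (2 of 11, Penk and Slc32a1) had adjusted p-values of 0.0182, 0.0257 and 0.00856, with an adjusted p of 0.170, 0.188 and 0.170 with an estimated correlation. Of 12466 genes tested 292 passed, 190 higher and 102 lower, 50 of them at least 2-fold higher and 3 at least 2-fold lower. The groups did not overlap for 5.24% of genes, where chance gives 0.952%. Without the library G37R 2 or 3 the count was 193 or 143, and without control 1, 2 or 4 it was 138, 156 or 186, while sample weights gave 522 and the replicate number as a block 49.

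In 8-month G37R oligodendrocyte libraries few genes differed from controls. Serpina3n rose to 97.2 ± 12.4 from 47.4 ± 8.08 (1.03, SE 0.12, n = 4 and 5, adjusted p = 0.00688), the filament genes Vim to 20.6 ± 2.21 from 10.8 ± 1.32 and Gfap to 208 ± 25.6 from 137 ± 9.25, and the NF-kB partner gene Bcl3 to 3.48 ± 0.979 from 0.960 ± 0.227. The pseudokinase gene Trib1 (0.73, SE 0.08) and the folate enzyme gene Aldh1l2 (0.59, SE 0.08) rose too. Of 7 reactive astrocyte genes 3 rose (adjusted p = 1.17e-05, and 0.195 with an estimated correlation). Added RNA from other cells was not tested for. Of the 13 genes past the threshold 6 lie within 20 Mb of Pla2g4e on chromosome 2, a region chosen from this result. In 10000 random draws of 13 tested genes, a permutation test added after that, 0 had as many within 20 Mb of any drawn gene (highest 5). They are the phospholipase gene Pla2g4e (119992147 to 120071071, 2.81 ± 0.414 against 0.485 ± 0.106), Gchfr, a regulator of tetrahydrobiopterin synthesis (3.30 ± 0.739 against 0.7501 ± 0.267), Sord, sorbitol dehydrogenase (15.8 ± 1.17 against 9.50 ± 1.10), the glucosidase gene Ganc (0.57, SE 0.08), the actin regulator gene Fmn1 (0.53, SE 0.08), and Aven, the single gene that fell (52.7 ± 4.36 against 85.02 ± 8.46). In astrocytes 13 genes of that region passed (5.6 expected, Fisher's test adjusted p = 0.0168). The fullest window anywhere held 16, as in 3740 of 10000 draws. In motor neurons 29 passed (30.3 expected), in 8-month spinal cord 7 (5.68) and in 11-month G37R oligodendrocytes 122 (111). In that spinal cord the fullest window, elsewhere, held 24 of 300 genes, as in 27 of 10000 draws, so clusters are not limited to this region.

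Camera called 14 other lists at 8 months, in none of which a member passed by limma, where 1279 genes had an unadjusted p under 0.05. Axonal cytoskeleton genes had a median of 0.29 (18 of 18 higher, Kif3a at 39.1 ± 1.87 against 31.8 ± 2.94), interferon genes 0.29 (14 of 14 higher), glutamate receptor and postsynaptic genes 0.21, nerve injury genes 0.21, complement genes 0.24 (C4b at 26.8 ± 1.48 against 15.7 ± 3.41), glycolysis genes 0.17 (7 rose adjusted over the list alone, such as Pfkp and Pfkm), calcium handling genes 0.16 and presynaptic genes 0.13. Their adjusted p-values in that order were 2.64e-05, 1.17e-05, 0.000262, 0.00575, 0.0113, 0.000575, 0.0322 and 0.0358. Myelin genes had a median of -0.09 (Mog at 751 ± 24.8 against 882 ± 89.6), ribosomal protein genes -0.12 (0 of 30 higher), cholesterol synthesis genes -0.13, ER chaperones -0.08, LXR targets -0.10 and proteasome genes -0.03, with adjusted p-values of 0.000262, 1.17e-05, 0.000110, 0.00616, 0.0280 and 0.0317. With an estimated correlation the adjusted p of these 14 lists lay between 0.421 and 0.782. Of 11935 genes tested 13 passed, 12 higher and 1 lower, among them Fmn1 and Uhrf1bp1l, which were named after their values were seen. The groups did not overlap for 4.43% of genes, where chance gives 1.59%. Without the library G37R 2 or G37R 3 the count was 7 or 8, and it was 25 with sample weights, 7 with the replicate block and 6 among genes with a mean of at least 5.

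**Figure D2:**
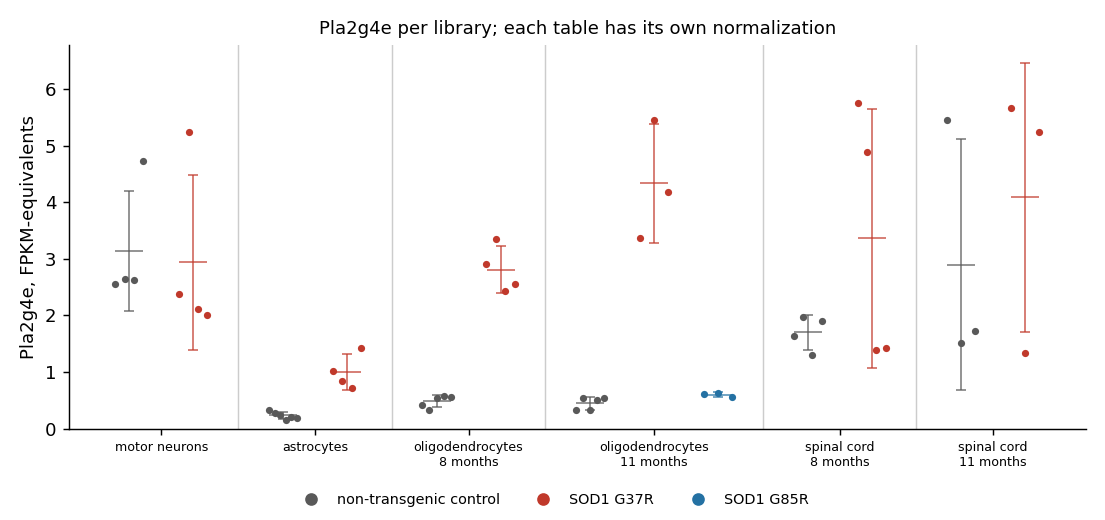
Level of Pla2g4e in each library (points, FPKM-equivalents) with the mean and SD of each of the 13 groups (bars). It split within groups in motor neurons and spinal cord.

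Oligodendrocytes of G37R mice at 11 months had less of the transcripts of myelin and more of those of other cell types. Mobp, a structural gene of myelin (chromosome 9, 120058859 to 120085209), was at 916 ± 295 against 1854 ± 78.4 (-1.06, SE 0.18, n = 3 and 5, adjusted p = 0.00206), and the myelin genes Mal (801 ± 218 against 1480.4 ± 144), Fa2h (-0.80, SE 0.12) and Mog (-0.78, SE 0.14) fell with it. Of 22 myelin genes 15 fell and 0 rose (17 fell adjusted over the list alone), with a median of -0.39, an adjusted p of 3.53e-05, and 0.622 with an estimated correlation. Of 9 oligodendrocyte precursor genes 3 fell, the lineage factor genes Olig1 and Olig2 and the enzyme gene Enpp6, and 1 rose, Neu4, with an adjusted p of 0.847 for a lower level where the median was 0.09 (adjusted p = 0.902 with an estimated correlation). The desaturase gene Scd1 (49.6 ± 10.3 against 111 ± 9.23), Srebf1, a regulator of lipid synthesis (-0.73, SE 0.11), and the cholesterol synthesis genes Insig1 (-0.89, SE 0.19), Dhcr7 and Sc5d fell too. Of 21 cholesterol synthesis genes 6 fell and 1 rose (adjusted p = 0.0368, 0.622 with an estimated correlation). Of 16 LXR targets 7 fell and 2 rose (adjusted p = 0.0913, 0.622 with an estimated correlation). Of 30 ribosomal protein genes 10 fell and 0 rose (8 adjusted over the list alone), with an adjusted p of 0.000492 (0.622 with an estimated correlation).

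Neuronal transcripts were higher in the same oligodendrocyte libraries. The neurofilament genes Nefm (595 ± 24.9 against 307 ± 20.8) and Nefh (1.06, SE 0.12) and the synaptic gene Snap25 (2620.1 ± 431 against 1464 ± 117) rose, as did Gad1, an enzyme of GABA synthesis (97.8 ± 18.4 against 42.1 ± 10.3). Of measured genes, 14 of 18 axonal, 13 of 20 presynaptic, 11 of 15 glutamate receptor, 13 of 19 ion channel, 10 of 13 motor neuron, 7 of 11 interneuron, 10 of 15 calcium handling and 8 of 16 nerve injury genes rose, and 0 fell but for 1 presynaptic gene and the channel gene Hcn2. The adjusted p-values in that order were 5.08e-06, 0.000278, 0.00119, 0.00289, 0.00204, 0.0142, 0.00356 and 0.00750. Of 21 glycolysis genes 17 rose and 1 fell, such as Ldha (96.0 ± 21.2 against 32.8 ± 4.19) and Pfkm (1.16, SE 0.23), with an adjusted p of 1.44e-05. Of 19 genes of fatty acid oxidation 10 rose and 2 fell, such as the lipid carrier gene Fabp7 (1.45, SE 0.40), with an adjusted p of 0.0368. With an estimated correlation each of these 10 lists had adjusted p = 0.622.

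Reactive and microglial transcripts were among the largest rises there. Lyz2 (chromosome 10, 116714596 to 116719328) was at 40.8 ± 22.4 against 2.37 ± 0.819 (3.49, SE 0.68, adjusted p = 0.00468), Lgals3 at 22.8 ± 9.08 against 2.26 ± 0.449, Serpina3n (chromosome 12, 105644917 to 105652539) at 413 ± 82.1 against 62.7 ± 10.8, and Vim at 88.6 ± 27.5 against 13.8 ± 2.43. The actin genes Capg (2.46, SE 0.42) and Tagln2 (2.32, SE 0.41) and the leukocyte gene Ptpn6 (2.18, SE 0.52) rose too. Of measured genes, 9 of 14 reactive astrocyte, 4 of 6 complement, 8 of 13 disease-associated microglia and 2 of 16 interferon genes (Psmb8 and Psmb9) rose and 0 fell, with adjusted p-values of 0.00211, 0.0368, 0.0146 and 0.0294, and an adjusted p of 0.622 with an estimated correlation for the former 3 lists and 0.663 for interferon genes. Of 13 homeostatic microglia markers 4 rose and 1 fell (adjusted p = 0.0851), of 23 lysosome genes 6 rose and 2 fell (0.351), and of 18 astrocyte homeostatic genes 3 rose, such as Aldh1l1 (1.22, SE 0.31), and 2 fell, such as the channel gene Kcnj10 (adjusted p = 0.251). With an estimated correlation their adjusted p was 0.663, 0.863 and 0.801.

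Stress genes of 11-month G37R oligodendrocyte libraries moved in both directions. Of 22 PERK/ATF4 genes 6 rose, such as Trib3 (1.92, SE 0.31), Atf3 (1.61, SE 0.39) and Asns, asparagine synthetase (1.11, SE 0.21), and 3 fell. Of 26 ER chaperones 8 fell, such as Edem1 and P4hb. Of 14 cytosolic heat shock genes 4 rose, such as Hspb1 (25.1 ± 6.53 against 6.25 ± 1.39). Of 27 proteasome genes 5 rose and 1 fell, of 13 NRF2 and metal response genes 5 rose, such as Hmox1 (0.84, SE 0.25), and of 11 p53 targets 1 rose, Plk2, and 2 fell. Of 32 genes of oxidative phosphorylation 10 rose, such as Atp5b (1702 ± 247 against 1045 ± 63.8), and 8 fell, such as Ndufa2 (-0.71, SE 0.18). Of 9 immediate early genes 4 rose, such as Fos (1.63, SE 0.33), and 1 fell, Jund. Camera called none of these 8 lists, with adjusted p-values of 0.276, 0.0835, 0.0959, 0.468, 0.304, 0.532, 0.747 and 0.330. Microglial markers had a median of 0.89 in the same libraries.

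Transcripts listed at 0 made up the largest falls. Celf4, a neuronal RNA-binding protein gene (chromosome 18, 25636120 to 25912484), was listed at 0 in all 3 G37R libraries, at 15.3, 15.05, 16.4, 19.4 and 20.2 in controls and at 25.9, 21.4 and 19.2 in G85R. Mir1199 was listed at 0 in all 3 G37R and all 3 G85R libraries and at 21.1, 22.5, 3.84, 13.5 and 16.05 in controls. The GABA receptor gene Gabrr2 (-1.54, SE 0.28) and the noncoding RNA gene Meg3 (-1.20, SE 0.33) fell. Of 11733 genes tested 5750 passed, 49.0%, with 3065 higher and 2685 lower, 212 of them at least 2-fold higher and 25 at least 2-fold lower. The groups did not overlap for 43.6% of genes, where chance gives 3.57%. Without the library G37R 2 or G37R 3 the count was 2959 or 2805, and with sample weights it was 8891.

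**Figure D3:**
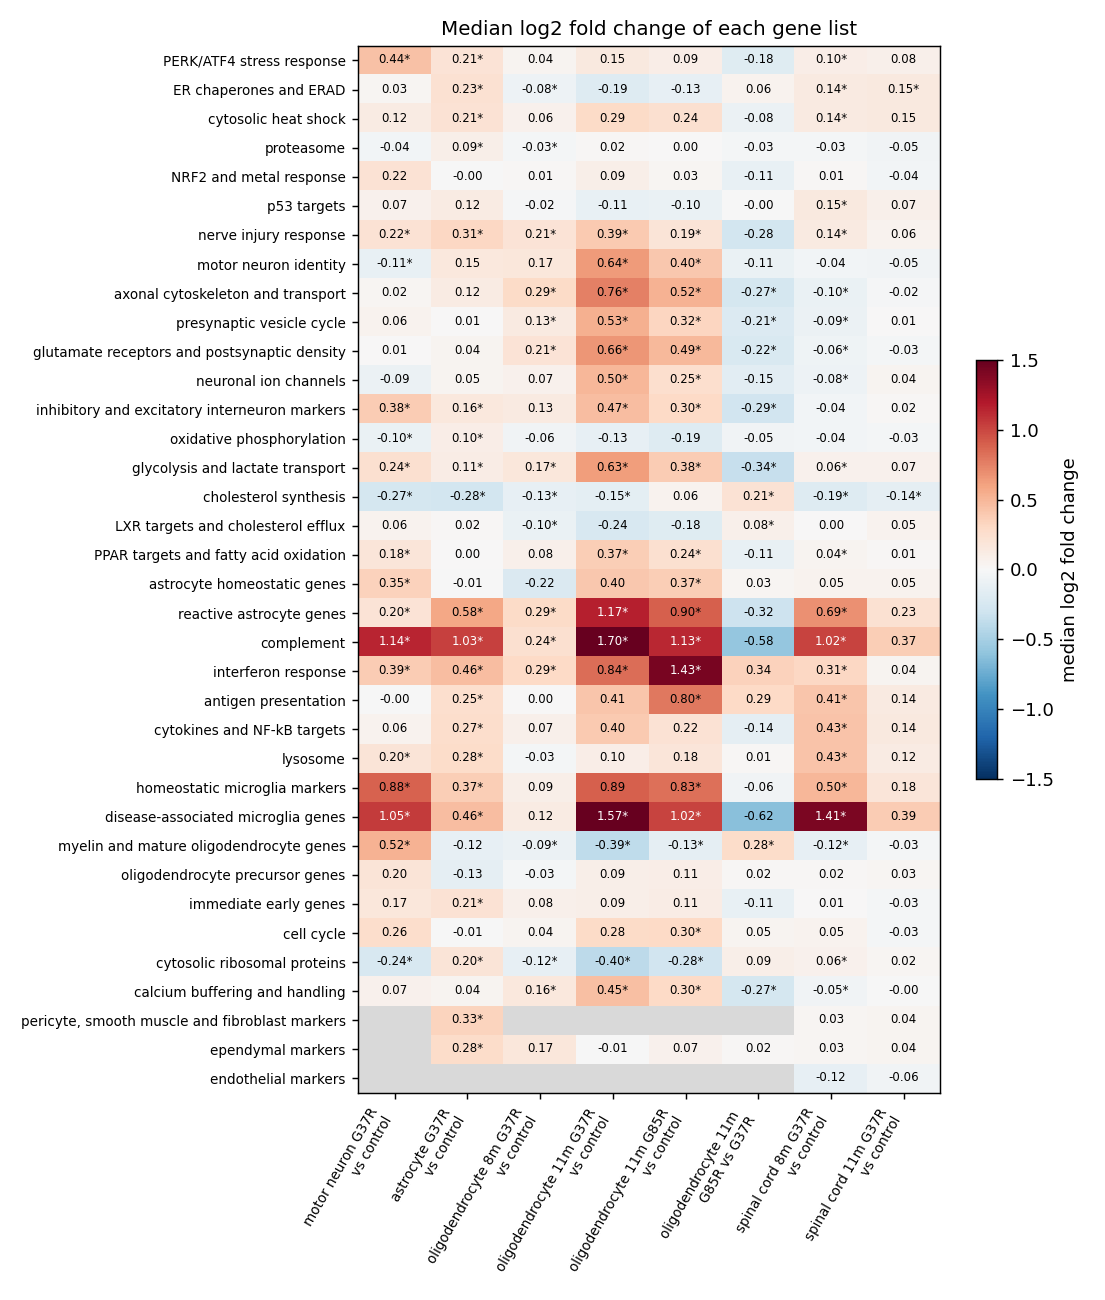
Median log2 change of each gene list with at least 5 measured members (colour) in each of the 8 comparisons, with an asterisk where camera's adjusted p was under 0.05 at a preset correlation of 0.01, and grey where fewer were measured. Disease-associated microglia genes had a median of 1.41 in 8-month spinal cord, and myelin genes of -0.39 in 11-month G37R oligodendrocytes.

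Oligodendrocytes of G85R mice at 11 months had 1 gene past the threshold. That gene was Mir1199, listed at 0 as given above (adjusted p = 0.0363). Nefm was at 478 ± 38.3 against 307 ± 20.8 (n = 3 and 5, adjusted p = 0.0753), Ahi1, a gene of primary cilia, at 93.8 ± 8.30 against 61.2 ± 4.42, Fam57a at 29.3 ± 1.48 against 39.5 ± 1.03 and the glutamate receptor gene Grm3 at 27.2 ± 1.55 against 36.4 ± 1.42 (adjusted p = 0.0911 each). Mobp was at 1171 ± 227 against 1854 ± 78.4 and the gap junction gene Gjb1 at 261 ± 34.9 against 358 ± 29.2. The exchanger gene Slc8a1 was listed at 0 in the 3 G85R libraries, at 3.12, 2.99, 3.87, 5.26 and 5.36 in controls and at 4.57, 6.33 and 0 in G37R. The library labelled G85R 1 stood apart, and is the only library of its group labelled male, so its distance is not separated from sex. It had Gfap at 901, against 196 and 321 in the other G85R libraries and 132 to 209 in controls. It had Serpina3n at 1001 against 84.8 and 142 and Cst7 at 6.33 against 0.182 and 0.390. It also had more of the transcripts of complement and interferon, whose means carry SDs near their size (Irf9, a factor of the interferon response, 14.9 ± 15.2 against 3.26 ± 0.587).

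Camera called 20 lists for G85R, with 0 members past the threshold by limma over all genes. Axonal genes had a median of 0.52 (13 rose adjusted over the list alone), interferon genes 1.43 (15), glycolysis genes 0.38 (13, with Ldha at 68.2 ± 27.3 against 32.8 ± 4.19), motor neuron genes 0.40 (7, with Nefh at 198 ± 32.4 against 115 ± 10.7), presynaptic genes 0.32 (8), glutamate receptor genes 0.49 (8), interneuron markers 0.30 (3) and calcium handling genes 0.30 (5 rose and 1 fell). Their adjusted p-values in that order were 1.39e-07, 6.73e-06, 7.34e-06, 1.49e-05, 0.000479, 0.000479, 0.0462 and 0.0203. Ion channels had a median of 0.25, nerve injury genes 0.19, fatty acid oxidation genes 0.24 (1 rose and 1 fell), cell cycle genes 0.30 (1) and antigen presentation genes 0.80 (1), with adjusted p-values of 0.00411, 0.0123, 0.0143, 0.0190 and 0.0101. Reactive astrocyte genes had a median of 0.90, complement 1.13, homeostatic microglia 0.83, disease-associated microglia 1.02 and astrocyte homeostatic genes 0.37, with adjusted p-values of 0.000479, 0.0203, 0.0143, 0.00445 and 0.0226. These 5 medians rest largely on the library G85R 1. Without it, a choice made by its values after the data were seen, they were 0.29, 0.17, 0.13, 0.27 and -0.03 in that order, with adjusted p-values of 0.0124, 0.276, 0.365, 0.149 and 0.731. Nerve injury, fatty acid oxidation and cell cycle genes fell to 0.08, 0.13 and 0.19 and were lost too (adjusted p = 0.127, 0.0859 and 0.0936). The interferon median fell to 0.49 and that of antigen presentation to 0.20 (adjusted p = 1.45e-09 and 0.0180). Axonal, motor neuron, presynaptic and glutamate receptor genes kept medians of 0.40, 0.33, 0.24 and 0.36 and passed, and 15 lists were called. Ribosomal protein genes had a median of -0.28 (adjusted p = 0.000134), and -0.15 without G85R 1. Myelin genes had a median of -0.13 and a mean of 0.02 (4 fell adjusted over the list alone, adjusted p = 0.0101 for a lower level). The adjusted p of the 20 lists lay, with an estimated correlation, between 0.535 and 0.607. Of 11733 genes 1 passed, 3778 had an unadjusted p under 0.05 (1545 without G85R 1) and 1280 an adjusted p under 0.1, and the groups did not overlap for 22.5%, where chance gives 3.57%. Without G85R 1, G85R 3 or control 1, 2, 4 or 5 the count was 0, and without G85R 2 it was 2, while sample weights gave 96, and the replicate block and sex as a covariate gave 0 each.

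G85R and G37R oligodendrocytes at 11 months differed in 5 genes. Celf4 was higher in G85R, at the values given above, as were Serinc5, a serine incorporator gene (64.8 ± 3.44 against 41.3 ± 3.23, n = 3 and 3, adjusted p = 0.0148), and Fam57a (29.3 ± 1.48 against 19.97 ± 1.38). Pla2g4e was at 0.601 ± 0.0417 in G85R and 4.33 ± 1.05 in G37R (-1.72, SE 0.13, adjusted p = 0.000307), and Fxyd7, a regulator of the sodium pump, at 73.8 ± 8.51 and 141 ± 10.1. Myelin genes had a median of 0.28, with 22 of 22 higher in G85R (Enpp2 at 528 ± 25.9 against 419 ± 0.551), and cholesterol synthesis genes 0.21, with adjusted p-values of 3.87e-07 and 7.60e-06 (0.621 each with an estimated correlation). LXR targets had a median of 0.08 (Scd1 at 79.2 ± 10.8 against 49.6 ± 10.3, adjusted p = 0.0328). Medians were -0.34 for glycolysis, -0.27 for axonal, -0.21 for presynaptic, -0.27 for calcium handling, -0.29 for interneuron and -0.22 for glutamate receptor genes, with adjusted p-values of 0.000149, 0.00143, 0.00184, 0.00184, 0.0171 and 0.0328. With an estimated correlation their adjusted p lay between 0.661 and 0.892. No member passed over all genes by limma, where 1621 of 11733 genes had an unadjusted p under 0.05. Of the 5 genes past the threshold 3 were higher and 2 lower, and the groups did not overlap for 16.9% of genes, where chance gives 10%. Without the library G85R 1 the count was 315 and 21 lists were called in place of 9, with LXR targets lost (adjusted p = 0.365). Complement genes then had a median of -1.56, disease-associated microglia genes -1.27, reactive astrocyte genes -0.97 and interferon genes -0.37, against 0.34 with it (adjusted p = 1.20e-05, 0.000126, 6.91e-09 and 0.000126). Without G85R 3 the count was 2, while quantile normalization gave 11, sample weights 3717 and the replicate block 2.

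Spinal cord of G37R mice at 8 months had more of the transcripts of microglia and inflammation. Lyz2 was at 85.4 ± 38.7 against 11.8 ± 3.30 (2.69, SE 0.37, n = 4 and 4, adjusted p = 0.0262), and the chemokine gene Ccl4 (chromosome 11, 83476085 to 83478185) at 4.70 ± 0.733 against 0.351 ± 0.208 (2.08, SE 0.12, adjusted p = 0.000162). Cst7 (2.30, SE 0.20), the receptor gene Clec7a (2.17, SE 0.24), Ccl3 (2.14, SE 0.20), Lgals3 (2.10, SE 0.20) and Gpnmb (1.74, SE 0.29) rose, as did Timp1 (2.19, SE 0.22) and the injury gene Sprr1a (5.25 ± 0.443 against 0.808 ± 0.398). Of 18 disease-associated microglia genes 14 rose, of 17 homeostatic microglia markers 8, of 23 lysosome genes 16, of 24 reactive astrocyte genes 14, of 10 complement genes 8 and of 11 antigen presentation genes 4, such as Cd74 (9.57 ± 1.49 against 2.55 ± 0.670), and 0 fell. Adjusted over the list alone 17, 11, 20, 21, 10 and 9 rose, with 1 homeostatic marker that fell. The adjusted p-values were 8.84e-26, 8.56e-12, 1.17e-23, 9.35e-24, 1.77e-14 and 8.31e-10, with an adjusted p of 0.110 (0.118 for antigen presentation) with an estimated correlation. Of 14 cytokine and NF-kB genes 5 rose, such as Cxcl10 (1.37, SE 0.10), and 1 fell, Nfkb2 (-0.52, SE 0.09), and of 16 interferon genes 2 rose, Bst2 and Psmb8, with adjusted p-values of 2.25e-07 and 8.75e-09 (0.110 and 0.210 with an estimated correlation). The cell types behind these transcripts cannot be read from whole tissue.

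Stress genes of spinal cord were higher and myelin genes lower by small amounts. Of 23 PERK/ATF4 genes 2 rose, Atf3 (1.07, SE 0.13) and Eif4ebp1, of 18 nerve injury genes 4 rose and 1 fell, Stmn4, of 14 heat shock genes 1 rose, Hspb1 (43.1 ± 5.83 against 19.99 ± 3.66), and of 16 LXR targets 4 rose, such as the lipoprotein gene Apoe (2357 ± 295 against 1655 ± 170), with adjusted p-values of 1.28e-05, 8.52e-06, 0.000109 and 0.116 (0.110, 0.110, 0.317 and 0.560 with an estimated correlation). Of 22 myelin genes 3 fell, Aspa (39.6 ± 3.44 against 50.5 ± 3.18), Gjb1 and Gal3st1 (8 adjusted over the list alone), with an adjusted p of 1.43e-05 (0.298 with an estimated correlation). Of 19 ion channel genes 1 fell, Kcna2, and of 21 glycolysis genes 2 rose, Slc16a3 and Hk2, with adjusted p-values of 8.52e-06 and 0.0381 (0.110 and 0.466 with an estimated correlation). No member passed by limma over all genes in the lists of cholesterol synthesis (median -0.19, 6 fell adjusted over the list alone), axonal (-0.10, 5 fell), presynaptic (-0.09), glutamate receptor (-0.06), calcium handling (-0.05), ER chaperone (0.14), p53 target (0.15), fatty acid oxidation (0.04) and ribosomal protein genes (0.06). Their adjusted p-values in that order were 4.75e-08, 0.000160, 8.22e-05, 0.00251, 0.0282, 4.76e-08, 0.000160, 0.0146 and 0.00287, and with an estimated correlation the adjusted p lay between 0.110 and 0.574. Microglial markers had a median of 0.50 in the same libraries.

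The largest fall in 8-month spinal cord was Mir382, listed at 0 in all 4 G37R libraries and at 52.9, 51.9, 62.5 and 105.9 in controls. Serpinb1a, a protease inhibitor gene (22.5 ± 2.65 against 34.0 ± 3.08), the homeobox gene Nkx2-9 (-0.49, SE 0.10) and Plekhh1 (-0.32, SE 0.06) fell too. Of 13828 genes tested 300 passed, 259 higher and 41 lower, 47 of them at least 2-fold higher and 1 at least 2-fold lower. The groups did not overlap for 9.94% of genes, where chance gives 2.86%. Without G37R 1, 2, 3 or 4 the count was 482, 103, 151 or 137, and without control 1, 3 or 4 it was 90, 164 or 80, while the replicate block gave 91 and a mean of at least 5 gave 135.

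In spinal cord at 11 months 3 genes passed between the libraries labelled G37R and control, all listed at or near 0 in the 3 controls. The small nucleolar RNA genes Snord100 (chromosome 10, 23505559 to 23505627) and Snora75 were listed at 185, 173 and 159 and at 12.2, 22.8 and 21.0 in G37R, and the ribosomal protein pseudogene Rpl34-ps1 at 9.54, 7.47 and 15.4 against 0.00478, 0.00430 and 0.00361. At 8 months Snord100 was listed at 0 in 1 of 4 controls and 2 of 4 G37R libraries. Trim59 was at 11.2 ± 1.34 against 18.8 ± 0.872 (n = 3 and 3, adjusted p = 0.194) and the hemoglobin gene Hba-a1 at 105 ± 9.50 against 72.4 ± 2.41 (adjusted p = 0.404). ER chaperones had a median of 0.15 (Hyou1 at 29.2 ± 1.74 against 24.8 ± 0.343) and cholesterol synthesis genes of -0.14, 0 members past by limma, with adjusted p-values of 0.000407 and 0.0162 (0.975 each with an estimated correlation).

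Libraries of 11-month spinal cord did not sort by their labels on the genes of the 8-month difference. The mean log2 level of the 259 genes that rose at 8 months was 4.26 in the library labelled control 1 and 3.09 and 3.00 in the other controls, and 3.80, 3.08 and 4.08 in those labelled G37R 1, 2 and 3. At 8 months it was 2.79 to 2.92 in controls and 3.33 to 3.70 in G37R. A check of sex against the labels, chosen after the values were seen, found 2 of these 6 libraries that did not match, both controls and 1 of them control 1. An exchange of control 1 and G37R 2 is not shown by it. Of 13839 genes tested 3 passed, 3 higher and 0 lower, 742 had an unadjusted p under 0.05, and the groups did not overlap for 12.3%, where chance gives 10%. Without G37R 1, 2 or 3 the count was 10, 7 or 9, and it was 0 with near-zero values as missing and 241 with the libraries labelled control 1 and G37R 2 left out, both chosen after seeing the data, the latter by values of the libraries.

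**Figure D4:**
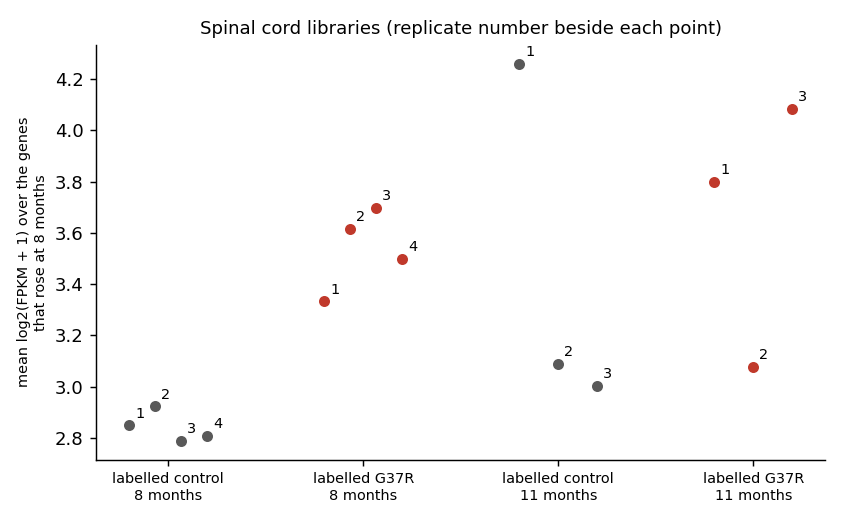
Mean log2(value + 1) over the 259 genes that rose in 8-month spinal cord, for each spinal cord library by group, with its replicate number. At 11 months control 1 and G37R 2 lie beside libraries of the other group.

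G37R effects differed between cell types and oligodendrocyte stages. Between motor neurons and astrocytes 322 of 11380 genes differed, 215 effects higher in motor neurons and 107 lower. Atf3 changed by 2.46 in motor neurons and 0.64 in astrocytes (difference 1.83, SE 0.23, adjusted p = 0.000680), and Hspb1 by 0.09 and 2.67 (difference -2.58, SE 0.23, adjusted p = 1.29e-05). The AP-1 genes Maff (-1.41, SE 0.16) and Junb (-1.09, SE 0.16) and the genes Tinf2 and Anxa2 had the higher effect in astrocytes, and Fam123a (1.33, SE 0.19), Plekho2 (1.12, SE 0.16), the chloride channel gene Clic4 and Aven in motor neurons. Between motor neurons and 8-month oligodendrocytes 130 of 11304 genes differed, 52 and 78. Nupr1 had the higher effect in motor neurons (1.66, SE 0.20) and Tcp11l1 in oligodendrocytes (-1.03, SE 0.12). Between astrocytes and 8-month oligodendrocytes 56 of 11461 differed, 29 and 27, with Hspb1 higher in astrocytes (2.38, SE 0.23) and Sall2 in oligodendrocytes (-1.18, SE 0.16).

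Between 11-month and 8-month oligodendrocytes 1650 of 11551 genes differed in the G37R effect, 836 higher at 11 months and 814 lower. Stage and sex are not separated there. The chromatin remodeller gene Smarca2 changed by 0.73 at 11 months and 0.09 at 8 months (difference 0.64, SE 0.10, adjusted p = 0.00413). Celf4, listed at 0 in G37R at 11 months alone, and Fam57a (-0.81, SE 0.10) had the lower effect. Between 11-month and 8-month spinal cord 0 of 13590 genes differed by limma, where 872 had an unadjusted p under 0.05 and the lowest adjusted p was 0.770. The smallest p-values were those of Tmx3 (-0.27), Tesk1 (0.32), Rpl34-ps1 (2.74), Mob4 (-0.30) and Ufm1 (-0.22).

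Counts of these differences moved with single libraries, as in these examples. Between motor neurons and astrocytes the count was 108 or 126 without motor neuron G37R 3 or 4, 114, 122 or 182 without motor neuron control 2, 3 or 4, 157 or 1590 without astrocyte G37R 3 or 4, and 171 or 491 without astrocyte control 2 or 5. Between motor neurons and oligodendrocytes it was 319, 262, 25 or 57 without motor neuron G37R 1 to 4, 32, 34 or 38 without motor neuron control 2, 3 or 4, 22 without oligodendrocyte G37R 1, and 248 or 229 without oligodendrocyte control 3 or 5. Between astrocytes and oligodendrocytes it was 37 or 626 without astrocyte G37R 3 or 4, and 27, 22 or 21 without oligodendrocyte G37R 1, 2 or 4. Between the stages of oligodendrocytes it was 799 without 8-month G37R 3, 3301, 453 or 326 without 11-month G37R 1 to 3, and 862 without 11-month control 2. Between the stages of spinal cord it was 1 without 11-month control 1 or control 2.

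Log2 changes were set against each other across genes for 11 pairs of comparisons, and genes are not independent replicates. The highest Pearson r was that of G37R and G85R in 11-month oligodendrocytes, 0.83, where the shared controls alone gave 0.378 in simulation and controls split between both gave 0.489 to 0.735. The 8-month and 11-month effects of G37R in oligodendrocytes had r = 0.49, and 10 of the 10 genes that rose at 8 months and were tested at 11 months rose there too, where 2.56 were expected. Astrocytes and 8-month spinal cord had r = 0.31 and 68 shared genes that rose, where 2.54 were expected. For 11-month G37R oligodendrocytes r was 0.26 with motor neurons and 0.23 with 8-month spinal cord, where Spearman's rho was -0.03. Motor neurons had r = 0.15 with astrocytes, 0.12 with 8-month oligodendrocytes and 0.06 with 8-month spinal cord. The r of 8-month oligodendrocytes was -0.07 with astrocytes and -0.02 with 8-month spinal cord, and that of the spinal cord stages was 0.02. There rho was 0.24, and 91% of the genes past the threshold at 8 months had the same sign at 11 months, so the low r does not show that the stages are unrelated.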

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

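The tests of the transgene, of the 11-month spinal cord labels, of the larger lists alone and of separate controls were chosen only after the results were seen, while those of the chromosome 2 segment and of the other cell types over all lists were set beforehand.

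Genes near Pla2g4e on chromosome 2 differed between genotypes. Pla2g4e was high in all G37R astrocyte and oligodendrocyte libraries and not in G85R. In 8-month spinal cord it was at 5.75, 4.88, 1.39 and 1.42 in G37R 1 to 4. Of these 2 lie within the control range of 1.30 to 1.96. That restates the pattern, for Pla2g4e alone, so the transgene stays open. In motor neurons control 4 (4.72) and G37R 2 (5.25) were high, so the level did not follow genotype. Their Gchfr was high too (20.8 and 18.9, others 7.08 to 10.3), but not Aven. A candidate is a chromosome 2 segment that differs between mice, tested by how many of the 50 genes correlating most with Pla2g4e within groups lie within 20 Mb of it, with at least 10 asked for and at most 3 against it. There were 6 in motor neurons, 5 in 8-month and 0 in 11-month spinal cord (0.955, 0.944 and 0.947 expected). In 11-month spinal cord it followed the doubted libraries (controls 5.46, 1.51 and 1.72, G37R 5.67, 1.34 and 5.24), so the 0 decides nothing. The segment stays open, as do a variant against the build and the background of each line.

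In 11-month spinal cord the libraries labelled control 1 and G37R 2 lay with the other group. Exchanged or mislabelled libraries are a candidate explanation that stays open. The score cannot test it, since the libraries were picked on it. In sex-linked transcripts 2 controls did not match their labels, and 2 libraries still did not if the labels of control 1 and G37R 2 are exchanged. An exchange within the controls would leave 0 and not touch the groups, while moving 3 labels, G37R 2 among them, would leave 0 and change the groups. Control 1 lay 1.21 above the mean of the other controls, where the G37R effect at 8 months was 0.694. It lay 1.17 above control 2, alike in sex-linked transcripts, and G37R 3, female by its label as well, lay 1.01 above G37R 2. Both were picked on this score, so these gaps cannot exclude a slow disease course in 1 G37R mouse or a sex difference. The groups were kept as labelled, and illness of the control 1 animal stays open and untested.

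Transcripts of other cell types were higher in purified G37R libraries, and a larger share of RNA from all other cells was taken to raise all markers alike. In motor neurons homeostatic microglia markers (median 0.88) exceeded endothelial markers by 0.799 (SE 0.289) and in 11-month oligodendrocytes by 1.04 (SE 0.409), which met the bound set beforehand of more than 2 SE. That bound was not used, since the endothelial list had 2 members, below the minimum of 5 preset for lists, and the limit to larger lists and the way the tests were combined were set after these values were known. With lists of at least 5 members the gap was 0.674 (SE 0.284) in motor neurons, microglia against oligodendrocyte precursors. It was 0.515 (SE 0.271) in oligodendrocytes, microglia against astrocytes. These pairs are extremes with unlike control levels, so the gaps decide nothing. Such a share and a change in microglia stay open in both, alone or together.

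Single libraries far from the rest of their group were looked for in 643 sets of values, where chance gives about 32.2 at 1 in 20, and 24 were found. In motor neurons they were Sprr1a in G37R 2 (62.5) and Camk2a in G37R 4 (15.5), Kcnk9, Syt2 and Pfkm in control 1 (12.7, 44.1 and 148) and Timp1 and Ifi27l1 in control 2 (1.21 and 139.5). In astrocytes they were Glul and Kcnj8 in G37R 1 (1955 and 2.997), Egr1 in control 3 (3.10) and Rps14 in control 5 (1291). In 8-month oligodendrocytes they were Pfkp and Pfkm in G37R 2 (79.3 and 181), Sord in control 1 (11.4), Aven in control 3 (70.3) and Nefm in control 5 (348). In 11-month oligodendrocytes they were Trib3 in control 1 (0.0959), Mobp in control 3 (1718), Ryr2 in control 4 (2.36) and Cst7 in control 5 (0.0791). In 8-month spinal cord they were Plekhh1 in G37R 4 (23.7) and control 2 (31.1), Slc16a3 in control 1 (1.13) and Cd68 in control 2 (9.82).

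Differences of G37R effects were taken for 10 genes per contrast. Between 11-month and 8-month oligodendrocytes the differences were 0.64 for Smarca2, 0.72 for Fam40a, 1.002 for Rusc1, 0.61 for Kbtbd4, 0.90 for Ak4, -4.43 for Celf4 (listed at 0 in 11-month G37R), -0.81 for Fam57a, -0.68 for Ppp1r16b, -0.82 for Gng12 and -0.62 for 2510006D16Rik. Between motor neurons and astrocytes they were 1.83 for Atf3, 1.33 for Fam123a, 1.12 for Plekho2, 1.04 for Clic4, 0.84 for Aven, -2.585 for Hspb1, -1.41 for Maff, -1.02 for Tinf2, -0.91 for Anxa2 and -1.09 for Junb. Between motor neurons and 8-month oligodendrocytes they were 1.66 for Nupr1, 0.80 for Ifrd1, 1.34 for C1qtnf5, 0.61 for Mthfd2, 0.88 for Carhsp1, -1.03 for Tcp11l1, -0.64 for Fmn1, -0.86 for Sord, -0.65 for Smc4 and -0.91 for Rora. Between astrocytes and 8-month oligodendrocytes they were 2.38 for Hspb1, 1.23 for Fcgr3, 1.04 for Olfml3, 1.52 for Mthfd2, 1.36 for Maff, -1.18 for Sall2, -0.9996 for Sord, -0.93 for Plekho2, -0.86 for Bcar3 and -0.68 for Atl2.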

How the results depend on the processing

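The alternatives that took near-zero values as missing, left out doubted libraries, for genes or lists, or left Ifi27 unmatched were chosen only after the results were seen. The cause of a change was not tested except where fewer genes or fewer libraries entered the fit.

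Counts of changed genes kept within 1.5 times under another pseudocount, median scaling and no robust estimation in all 8 comparisons. Sample weights gave 522 in astrocytes (292 before), 25 in 8-month oligodendrocytes (13), 8891 for G37R (5750) and 96 for G85R (1) in 11-month oligodendrocytes and 3717 between the mutations (5). Quantile normalization gave 11 between the mutations, 4 higher and 7 lower, against 3 and 2. A mean of at least 5 left 6 genes in 8-month oligodendrocytes, 135 in 8-month spinal cord, and 158, 34 and 29 for the differences of motor neurons from astrocytes, motor neurons from oligodendrocytes and astrocytes from oligodendrocytes, with fewer genes tested. Without a minimum level the last 2 were 215 and 109, and the difference between the stages of spinal cord was 2, against 0. A pseudocount of 0.1 gave 1 for that difference. Sex as a covariate gave 0 for G85R.

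The replicate number as a block gave 810 in motor neurons (1582), 49 in astrocytes, 7 in 8-month oligodendrocytes, 0 for G85R, 2 between the mutations and 91 in 8-month spinal cord (300). The labels do not say that equal numbers mark pairs. Correlations of equal numbers within groups lay between -0.265 and 0.352, and other numbers reached 0.320.

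Near-zero values as missing gave 0 in 11-month spinal cord (3), whose genes were all listed at or near 0 in controls. With the libraries labelled control 1 and G37R 2 left out, both picked by their values, the count there was 241, 230 higher and 11 lower, and the difference between stages was 2. With motor neuron G37R 3 and 4 left out, picked by their values, the count was 261, with fewer libraries.

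Leaving out each library in turn, the counts ran from 274 (without control 2) to 2136 (without G37R 1) in motor neurons, 138 (control 1) to 296 in astrocytes, 7 (G37R 2) to 17 in 8-month oligodendrocytes, 2805 (G37R 3) to 6549 for G37R and 0 to 2 (G85R 2) for G85R in 11-month oligodendrocytes, 2 (G85R 3) to 315 (G85R 1) between the mutations, 80 (control 4) to 482 (G37R 1) in 8-month spinal cord and 4 (control 2) to 10 (G37R 1) in 11-month spinal cord. Differences of effects ran from 326 to 3301 between the stages of oligodendrocytes, 0 to 1 between those of spinal cord, 108 to 1590 between motor neurons and astrocytes, 22 to 319 between motor neurons and oligodendrocytes and 21 to 626 between astrocytes and oligodendrocytes. Lists were tested with 1 library left out, G85R 1, picked by its values, which gave 15 for G85R (20) and 21 between the mutations (9).

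Lists rested on the preset correlation. With an estimated correlation 0 lists passed in each of the 8 comparisons by camera, against 17 in motor neurons, 21 in astrocytes, 15 in 8-month oligodendrocytes, 17 for G37R and 20 for G85R in 11-month oligodendrocytes, 9 between the mutations, 23 in 8-month and 2 in 11-month spinal cord. Fry gave 11, 13, 1, 19, 0, 0, 14 and 0 in that order, and fry in either direction gave 29 in motor neurons, 2 in 8-month oligodendrocytes, 28 for G37R, 6 for G85R, 0 between the mutations and 0 in 11-month spinal cord. Camera with the replicate block gave 6 in 11-month spinal cord. Leaving Ifi27 unmatched moved no count. The relation of motor neurons and 8-month spinal cord turned from r = 0.0592 to -0.0636 at a mean of at least 5, and that of 11-month G37R oligodendrocytes and 8-month spinal cord moved from 0.23 to 0.13. That of the spinal cord stages went from 0.0151 to -0.0122 with a pseudocount of 0.1 and -0.0223 at a mean of at least 5.

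Over named genes and alternatives 8549 results kept their side of the threshold, 934 kept direction alone and 55 newly passed. Of those past it in either fit 0 turned. For the lists called at first 530 kept direction and threshold, 234 camera's direction alone and 0 turned, and lists called anew enter only the counts above. Among those not called at first, interferon, lysosome and astrocyte homeostatic genes between the mutations turned without G85R 1 and were then called, and others turned without a call. Of the 79 named genes past the threshold in motor neurons 24 kept that side whichever library was left out, of 52 in astrocytes 36, of 11 in 8-month oligodendrocytes 7, of 126 for G37R in 11-month oligodendrocytes 79, of 5 between the mutations 2 (Celf4 and Pla2g4e), of 52 in 8-month spinal cord 15 and of 3 in 11-month spinal cord 1 (Snord100), while Mir1199 in G85R was lost without control 1.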

Other observations

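Cholesterol synthesis genes, which make the sterol of membranes and myelin, were lower at the median in each of the 6 comparisons of G37R with control. The medians were -0.27 in motor neurons (2 of 21 genes higher), -0.28 in astrocytes (3), -0.13 and -0.15 in 8-month and 11-month oligodendrocytes (3 and 5) and -0.19 and -0.14 in 8-month and 11-month spinal cord (1 and 2), the latter with 2 labels in doubt. In G85R oligodendrocytes the median was 0.06, with 11 of 21 higher. With an estimated correlation its adjusted p ran from 0.270 to 0.975, and whether these 6 effects differ was not tested. Between the mutations the median was 0.21 (adjusted p = 7.60e-06, and 0.621 with an estimated correlation). Ribosomal protein genes had medians of -0.24 in motor neurons (15 of 30 fell), 0.20 in astrocytes and -0.12 in 8-month oligodendrocytes (0 of 30 past the threshold by limma in each of these 2). The adjusted p was 0.345 to 0.574 with an estimated correlation, and here too a difference between cell types was not tested.

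The following stress and reactive genes were chosen after their values were seen. Serpina3n, a protease inhibitor of reactive astrocytes, changed by 0.25 in motor neurons, 1.46 in astrocytes, 1.03 and 2.70 in 8-month and 11-month oligodendrocytes and 1.503 in 8-month spinal cord (adjusted p = 0.0429, 0.00403, 0.00688, 0.0104 and 0.0254). Hspb1, a small heat shock protein gene, was at 279 ± 7.63 against 264 ± 29.4 in motor neurons (adjusted p = 0.429), where its control level was above that of astrocytes (36.6 ± 6.40), across tables normalized separately. Atf3 rose in motor neurons, astrocytes, 11-month oligodendrocytes and 8-month spinal cord (2.46, 0.64, 1.61 and 1.07). In 8-month oligodendrocytes it lay under the minimum level and was not tested, at 0.759 ± 0.187 against 0.250 ± 0.0839 with no overlap.

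In the hypotheses below the test with separate controls was chosen only after the result was seen, and the splits and the test with the same controls were set beforehand. RNA from the surrounding spinal cord may add to the G37R libraries. Across genes, which are not independent replicates, the change in G37R was set against the log2 ratio of spinal cord to purified control level, with r of at least 0.3 asked for and at most 0 against it. With the same controls behind both values r was 0.572 in 11-month oligodendrocytes and 0.373 in motor neurons, which decides nothing, since shared controls alone make it positive. With other control libraries behind each it was 0.578 in oligodendrocytes, where 2525 genes at least 2-fold lower in purified controls than in spinal cord had a median change of 0.39 (1353 rose, 46 fell) and 1601 at least 2-fold higher had -0.42 (26 rose, 996 fell). Such RNA is therefore a candidate explanation for much of the 11-month change, myelin and neuronal genes included. In motor neurons r was 0.262, between the bounds, with medians of 0.14 over 2324 genes (313 rose, 56 fell) and -0.10 over 2242 (24 rose, 371 fell), so it stays open there. A loss of cell identity would give the same pattern and was not tested.

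Other splits of the same libraries were counted. In motor neurons 1 of 35 splits, the labelled one, gave as many as 1582 genes (highest other 2). In 8-month oligodendrocytes 1 of 100 gave 13 (2) and in 8-month spinal cord 1 of 35 gave 300 (40). In 11-month G37R oligodendrocytes 1 of 56 gave 5750 (3232). Each is under 0.05 for that test alone. In astrocytes 3 of 100 gave 292, with 1686 when control 5 was put with G37R 1, 2 and 3 in place of G37R 4, which points to a structure of the samples. For G85R against control 4 of 56 gave 1 (highest other 1223), so chance is not excluded. The 3232 and 1223 had controls 1, 2 and 3 apart, again such a structure. With 10 splits, too few for a share under 0.05, G85R against G37R had 5 genes and the highest other 2953 (2 gave as many). In 11-month spinal cord the numbers were 3 and 598 (4 gave as many). Differences of effects were as large in 3 of 100 splits between the stages of oligodendrocytes (1650, highest other 2563), 4 of 100 between motor neurons and astrocytes (322, 1371), 2 of 100 between motor neurons and oligodendrocytes (130, 255) and 1 of 100 between astrocytes and oligodendrocytes (56, 1), each under 0.05 for that test alone. Splits that gave more point to such a structure. Between the stages of spinal cord the labelled count was 0, which every split reaches by construction, so they decide nothing (highest other 1108).

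As many lists passed in 3 of 100 astrocyte splits (21, highest other 21), under 0.05 for that test alone. They did in 4 of 35 in motor neurons (17, 18) and 26 of 100 in 8-month oligodendrocytes (15, 21). In 11-month oligodendrocytes 9 of 56 did for G37R (17, 21) and 11 of 56 for G85R (20, 22). In 8-month spinal cord 4 of 35 did (23, 25). These do not exclude chance. Between the mutations 10 splits, too few for 0.05, gave 9 and 19 (9 as many). In 11-month spinal cord 10 splits gave 2 and 30 (10 as many). Other splits called 10 to 19 lists at the median.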
